A study of Mus musculus with 12 samples.

How the data were processed

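RNA was sequenced from 12 cultures of mouse pancreatic ductal adenocarcinoma cells: 3 independent lines (iKPC-1, iKPC-3, iKPC-5), each in 4 groups (GFP on dox, GFP off dox, wild-type USP21 off dox and enzyme-dead USP21 off dox). Per the labels, doxycycline at 1 µg/ml switched on KRAS*, cells were grown in Matrigel and total RNA was extracted. The labels give no time off dox and do not say from which species the USP21 sequence came. Groups and cell lines were taken from the sample titles, and each title matched 1 column of the table.

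The values are raw read counts per gene symbol, deposited by the authors as 1 table of 26073 genes in 12 columns. The notes on processing list CASAVA, STAR, TopHat, Cufflinks and HTSeq and the genome build mm9, with no versions and no roles, and do not state the annotation, the filters or the strand setting. Positions are therefore not given, and reads of overlapping or antisense genes cannot be told apart. Of the symbols, 27 had been turned into dates by a spreadsheet, which hides the names of those genes, 21 of which were tested. They were kept in the tests but not named, and repeated symbols were kept as separate genes. Total counts ran from 79719690 to 110344573 reads per library. In a library, 3 reads, the upper limit that a count of 0 allows, correspond to 0.0260 to 0.0378 CPM. Intervals and such floors cover counting error only, since copies made by PCR are not independent molecules.

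Genes were filtered with edgeR's filterByExpr by group (its default minimum count of 10 and minimum total of 15), which left 17064 genes, and libraries were scaled by TMM. Differences were tested in edgeR 4.0.16 under R 4.3.3 with the quasi-likelihood F test, two-sided, in 1 fit of all 12 libraries with 4 group means, with Benjamini-Hochberg adjustment over all genes tested in a comparison and a threshold of 0.05. CPM are TMM-scaled, and log2 CPM used a prior count of 2. The SE of a log2 fold change is the one that the F statistic implies. There were 4 comparisons: GFP off dox against GFP on dox (KRAS* extinction), each form of USP21 against GFP off dox, and wild-type against enzyme-dead USP21.

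Since each cell line is in every group, the lines pair the samples. The labels give this pairing, and it was checked on the deviations of log2 CPM from the group means: they correlated at 0.605 to 0.889 over the 18 pairs of libraries of the same line and at -0.651 to 0.045 over the 36 pairs of libraries of different lines. A second fit with the cell line as a block was therefore read beside the first. The fit without the block had been chosen as the first one in advance and was kept as such.

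A set of 26 gene lists with 670 distinct genes covered pathways, other cell types (fibroblasts, leukocytes, endothelium, pancreatic acini and islets) and signs of RNA quality and handling (histone genes, ribosomal proteins, immediate early genes). Lists were tested with limma 3.58.1 on voom values by camera with a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 26 lists of a comparison, then by camera with a correlation estimated from the data, and by fry. Camera called 14, 12, 10 and 15 lists in the 4 comparisons, and 0 of these calls held with an estimated correlation, with which the smallest adjusted p was 0.0706. Counts of members past edgeR's test are given over all genes and adjusted over the list alone.

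Genes were named by a rule: Kras, Usp21 and Trp53; then, for each comparison and direction, the 10 genes with the largest log2 fold change among those past the test, with a mean of at least 2 CPM, the same direction in all 3 lines and a symbol that is not a predicted gene model, filled up from the test with the block; then, for each list, up to 4 members with the largest change among those past the test, or past the block test, or else the 2 with the smallest p. The comparisons, tests, lists, naming rule and first set of alternatives were fixed before the data were examined. The relation between the effect of KRAS* and that of USP21 was measured as Pearson's r across genes in each line.

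The alternatives fixed in advance were RLE scaling, DESeq2 1.42.0, limma-voom, no filter, a filter of 1 CPM in 3 libraries, the cell line as a block in edgeR and in DESeq2, a fit of only the 2 groups compared, a prior count of 0.5 for the relation, and each library and each cell line left out in turn. Where a fit left out a whole line, 2 libraries per group remained. Chosen after seeing the data were scaling by total counts alone, the block fit without each line, the block fit with a correction for GC content and transcript length (splines with 5 degrees of freedom, 16040 of the 17064 genes matched to mouse transcripts), the block fit of the lists with an estimated correlation, and the relation without cell cycle genes, with GC and length correction and with total counts.

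The tests were tried on simulated counts in which 100 of 17064 genes were changed 2-fold and another 100 were changed 4-fold, with the spread of the real data. Without the block, edgeR recovered 14% to 27% of the 2-fold and 60% to 68% of the 4-fold changes with 0 false calls. With the block it recovered 68% to 73% and 88% to 96%, with 6 to 11 false calls. Each change was the same in all lines and the spread was that of the block fit, so effects that differ between lines were not tried. A further list of genes was raised to try camera and was left out of the false calls. Camera with the preset correlation called at most 1 of 100 unchanged lists at an unadjusted p under 0.05, but genes were simulated without correlation, which does not test that setting. No library was left out.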

Results

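Transcripts were measured by RNA sequencing in 12 libraries from 3 mouse pancreatic ductal adenocarcinoma lines grown in Matrigel, a basement membrane gel, and named iKPC-1, iKPC-3 and iKPC-5. In these lines doxycycline (dox, 1 µg/ml) switches on a mutant KRAS transgene, written KRAS*. Each line gave 1 library in each of 4 groups: GFP on dox, GFP off dox, wild-type USP21 off dox and enzyme-dead USP21 off dox, so that n = 3 per group. USP21 is a deubiquitinase, an enzyme that removes ubiquitin from proteins. The total count per library ran from 79719690 to 110344573 reads, and 17064 genes had enough reads to be tested. The 3 lines differ from one another: the first principal component held 39.1% of the variance and set iKPC-1 apart from iKPC-3 and iKPC-5, and the second held 28.0% and set the libraries on dox apart from those off dox. Since the replicates are 3 independent cell lines, each p of the first edgeR test measures an effect against the spread between lines. Values are CPM (counts-per-million, the read count scaled to the library size) with their SD, or log2 fold changes with their SE from edgeR. A second edgeR test included the cell line as a block, and values from it are named as such. The block takes out constant differences between lines, so its p measures an effect against the spread that remains. A camera p compares a gene list with other genes instead.

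Kras and Usp21 matched the labels in every library. Kras fell from 597 ± 113 CPM on dox to 36.3 ± 9.17 CPM off dox in the GFP cells (SD, n = 3), which is 16.4-fold (log2 fold change -4.04 ± 0.25 SE, adjusted p = 9.46e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). A count per gene symbol holds the reads of the endogenous gene and any that the transgene adds. Off dox, Kras stood at 46.0 ± 8.66 CPM with wild-type USP21 and 40.3 ± 6.89 CPM with enzyme-dead USP21. With the cell line as a block, Kras was higher with wild-type USP21 than with GFP by 0.35 ± 0.08 on the log2 scale (adjusted p = 0.0437, edgeR). Usp21 stood at 42.7 ± 3.6 CPM on dox and 54.0 ± 8.42 CPM off dox in GFP cells. It rose to 385 ± 58.4 CPM in cells given wild-type USP21 (log2 fold change 2.83 ± 0.30, adjusted p = 0.0479) and to 486 ± 234 CPM in cells given the enzyme-dead form (3.17 ± 0.31, adjusted p = 0.0196, both from edgeR). The enzyme-dead mean includes 1 library of iKPC-1 at 754 CPM. Between both forms Usp21 did not pass the edgeR test (log2 fold change -0.34 ± 0.28, adjusted p = 1). Trp53, which carries an engineered allele in these lines, ranged from 4.92 ± 0.278 to 6.92 ± 1.64 CPM over the group means and passed no test.

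**Figure D1:**
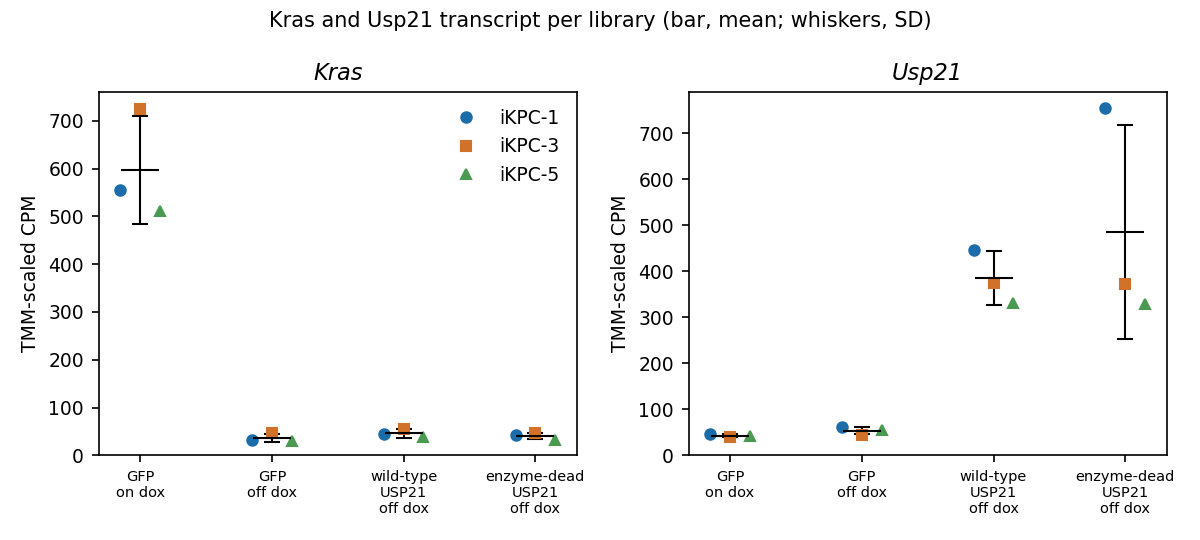
Kras (left) and Usp21 (right) in TMM-scaled CPM, per library (coloured points, 1 per cell line) with the group mean (bar) and SD (whiskers, n = 3), in the 4 groups. Kras averaged 597 CPM on dox against 36.3 CPM off dox in GFP cells, and Usp21 averaged 385 and 486 CPM in the cells given wild-type and enzyme-dead USP21.

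The first comparison, GFP cells off dox against GFP cells on dox, asks what loss of KRAS* expression changed. Dox was given to the GFP on dox cells alone, so effects of the drug itself cannot be told apart from those of KRAS*. Effects of KRAS* or of its extinction are meant in this sense throughout. When KRAS* was switched off, 24 of 30 targets of ERK signalling, 29 of 30 mitosis genes, 20 of 24 cholesterol synthesis genes and 9 of 31 NF-kappaB and cytokine genes fell, while the sterol transporter genes Abcg8 and Abcg5 and the mucus gene Fcgbp rose. Abcg8 and Abcg5, which pair to form a sterol exporter, rose most among the named genes, from 0.0203 ± 0.0152 to 34.6 ± 25.6 CPM and from 0.0451 ± 0.0486 to 36.4 ± 28.9 CPM (log2 fold change 10.67 ± 1.82, adjusted p = 0.00429, and 9.65 ± 1.97, adjusted p = 0.00892, edgeR). Fcgbp, a mucus component, rose from 0.366 ± 0.148 to 171 ± 110 CPM (8.87 ± 1.03, adjusted p = 0.00104, edgeR), and Lypd8, a protein of the colon surface, rose by 8.73 ± 1.34 (adjusted p = 0.00302, edgeR). The others of the 10 named for a rise were Mptx1, Clec2h, Edn1, Abhd3, S100g and Nr5a2, with log2 fold changes from 6.85 to 8.88. Among the genes that fell, Mmp13, a collagenase, went from 615 ± 805 to 3.87 ± 4.78 CPM, and Il6, an inflammatory cytokine, went from 13.6 ± 19.1 to 0.0212 ± 0.0124 CPM (log2 fold change -7.31 ± 2.05, adjusted p = 0.0316, and -9.26 ± 2.14, adjusted p = 0.0149, edgeR). Pla2g4e, a phospholipase, had 1 read in the 3 libraries off dox against 2136 reads on dox, a ratio of 2479-fold with a 95% exact binomial counting interval of 444 to 97960. Gp49a, Ccr1, Nox1, Tmem252, Sprr2h, Csf3 and Has2 completed the 10 named for a fall, with log2 fold changes from -10.42 to -6.99. Each of these 20 genes moved the same way in all 3 lines, which the naming rule required. In iKPC-1, Il6, Nox1 and Pla2g4e were low on dox already (0.05, 0.18 and 0.13 CPM), so their large falls rest on iKPC-3 and iKPC-5. Mptx1, Clec2h, Gp49a and Sprr2h belong to families of near-identical copies between which the counting could have split reads, so their values are uncertain.

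Of the 30 genes of ERK and RAS output, 24 fell and 0 rose, with 27 lower and 0 higher when adjusted over the list alone, 28 lower and 1 higher with the block, and a median log2 fold change of -2.01. Lif, a cytokine, fell by 5.52 on the log2 scale, Etv4, a transcription factor that ERK induces, fell by 4.77, Dusp5, a phosphatase that acts on ERK, fell by 4.07 and Fosl1, an AP-1 subunit, fell by 3.87. Limma's camera test set the list below other genes (adjusted p = 1.25e-15), but adjusted p = 0.238 with an estimated correlation. Mitosis genes fell as widely: 29 of 30 were lower and 0 higher (30 and 0 adjusted over the list alone and with the block), with a median of -1.89, camera adjusted p = 7.92e-19 and adjusted p = 0.376 with an estimated correlation. Bub1, a spindle checkpoint kinase, fell from 52.4 ± 7.53 to 8.39 ± 5.31 CPM and Ube2c, which marks mitotic regulators for destruction, fell from 85.3 ± 8.92 to 16.4 ± 7.94 CPM (SD, n = 3). S phase and DNA replication genes had 22 of 30 lower and 0 higher (29 and 0 adjusted over the list alone, 30 and 0 with the block), with Rrm2, a subunit of ribonucleotide reductase, down by a log2 fold change of -2.45. Its median was -1.43, with camera adjusted p = 4.74e-15 and adjusted p = 0.376 with an estimated correlation. Fry, which does not compare a list with other genes, gave adjusted p = 0.000969 for ERK and RAS output, 0.00405 for mitosis and 0.0053 for S phase. Cholesterol synthesis, described next, had 0.000443 by fry. Of the 14 lists that camera called on extinction, 8 passed fry.

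In cholesterol synthesis 20 of 24 genes were lower and 0 higher (23 and 0 adjusted over the list alone, 22 and 0 with the block), with a median of -2.15, camera adjusted p = 4.19e-16 and adjusted p = 0.238 with an estimated correlation. Idi1, which makes the isoprenoid unit, fell from 36.8 ± 2.46 to 3.65 ± 1.23 CPM, and Fdps, the next enzyme of that path, fell from 457 ± 86.2 to 58.4 ± 24.8 CPM. Among glycolysis, pentose phosphate and hexosamine genes 6 of 27 were lower and 0 higher (9 and 0 adjusted over the list alone, 17 and 1 with the block), among them the glucose transporter gene Slc2a1 and Ldha, which makes lactate, with log2 fold changes of -1.93 and -1.71. That list had a median of -0.85, camera adjusted p = 0.000226 and adjusted p = 0.376 with an estimated correlation. Of the 32 amino acid response and ATF4 targets 13 were lower and 1 higher (16 and 1 adjusted over the list alone, 20 and 2 with the block), including Psat1 of serine synthesis at -2.03, with a list median of -0.76, camera adjusted p = 2.66e-05 and adjusted p = 0.238 with an estimated correlation. MYC targets and ribosome biogenesis had 4 of 32 lower and 0 higher (3 and 0 adjusted over the list alone, 19 and 0 with the block), a median of -0.41, camera adjusted p = 2.66e-05 and adjusted p = 0.541 with an estimated correlation. Odc1, the first enzyme of polyamine synthesis, led that list at -1.59. Hypoxia genes had 6 of 23 lower and 0 higher (7 and 0 adjusted over the list alone, 13 and 2 with the block), a median of -1.31, camera adjusted p = 0.00181 and adjusted p = 0.558 with an estimated correlation.

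Mesenchymal markers fell in 7 of 24 genes and rose in 0 (the same counts adjusted over the list alone, 14 and 4 with the block), with Vim, which encodes vimentin, going from 5983 ± 771 to 1142 ± 223 CPM. Camera gave adjusted p = 0.0063 for this list, at a median of -1.17, and adjusted p = 0.376 with an estimated correlation. Epithelial markers had 5 of 31 higher, among them the epithelial transcription factors Ovol2 and Grhl2 (log2 fold changes 4.38 and 2.45), and 1 lower, the keratin gene Krt18 (-1.23). Those counts were the same adjusted over the list alone and became 16 and 5 with the block, and camera did not set the epithelial list apart (adjusted p = 0.203). NF-kappaB and cytokine genes had 9 of 31 lower and 0 higher, also when adjusted over the list alone (12 and 1 with the block), with Il1a and Ptgs2 at -6.55 and -5.35. Their median was -0.86, with camera adjusted p = 0.0436 and adjusted p = 0.558 with an estimated correlation. Interferon response genes had 6 of 31 higher and 1 lower (7 and 1 adjusted over the list alone, 16 and 1 with the block), including Irf1, an interferon-induced transcription factor, at 1.47. That list had a median of 0.70, camera adjusted p = 0.00214 and adjusted p = 0.541 with an estimated correlation. Wnt and TCF targets had 3 of 22 lower, Cd44, Ccnd1 and Myc, and 0 higher, also when adjusted over the list alone (7 and 1 with the block). Of these, Ccnd1 and Myc are also members of the ERK and RAS output list. The Wnt and TCF list missed the camera threshold (adjusted p = 0.0979) and passed it with the cell line as a block (adjusted p = 0.0377, but adjusted p = 0.562 with an estimated correlation). Genes used to judge the handling and quality of RNA moved as well: 8 of 20 immediate early and stress genes were lower and 1 higher (11 and 1 adjusted over the list alone, 11 and 3 with the block; median -0.61, camera adjusted p = 0.00309, adjusted p = 0.376 with an estimated correlation), with Egr3, an ERK-responsive gene, at -3.77.

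In all, edgeR called 1671 genes higher and 1871 lower of the 17064 tested. Of all tested genes, 6033 had an unadjusted p under 0.05, against 853 if no gene changed and p were uniform. With the cell line as a block edgeR called 4606 higher and 4199 lower, with all 3542 calls of the first test among them. Scaling by total counts alone gave 2896 higher and 1137 lower, since it moved the median log2 fold change of all genes from 0.042 to 0.296. Leaving out all libraries of iKPC-5 left 125 higher and 140 lower, and leaving out iKPC-3 left 421 and 692. Without single libraries the counts also moved by more than 1.5 times for iKPC-3 on dox (871 and 1188), iKPC-5 on dox (1068 higher), iKPC-1 off dox (1050 and 1181) and iKPC-5 off dox (779 and 942). Of the 97 named genes that passed, 71, 44 and 20 still passed without iKPC-1, iKPC-3 and iKPC-5 respectively. All kept their sign, which adds little since they were chosen for passing in these same libraries. With the block, 96, 87 and 81 of these 97 passed without the same lines. The NF-kappaB list missed the camera threshold without iKPC-5 (adjusted p = 0.297).

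The second comparison, wild-type USP21 against GFP, both off dox, asks what USP21 changed in cells without KRAS*. Usp21 itself was the 1 gene that passed the edgeR test, so the other genes in this paragraph and the next are named from the test with the cell line as a block. In that test 7 of 22 Wnt and TCF targets, 28 of 30 mitosis genes and 7 of 24 mesenchymal markers rose, and 7 of 31 epithelial markers fell. Axin2 and Lgr5, feedback targets of Wnt signalling, went from 0.601 ± 0.531 to 16.1 ± 11.1 CPM and from 0.401 ± 0.503 to 9.68 ± 5.76 CPM (SD, n = 3). Their log2 fold changes with the block were 4.91 ± 0.44 (adjusted p = 0.00438, edgeR) and 5.01 ± 0.79 (adjusted p = 0.0135, edgeR). Myl9, a myosin light chain of contractile cells, rose by 5.59 ± 0.86 (adjusted p = 0.0134, edgeR), and Enpp2, which makes lysophosphatidic acid, went from 21.1 ± 20.7 to 184 ± 141 CPM. Cdh16, Mmp9, Fgf18, Crlf1 and the Wnt ligand gene Wnt10a were the others named for a rise, with block log2 fold changes from 2.93 to 3.58. With wild-type USP21, Cdh16 stood at 41.1, 0.87 and 0.4 CPM in iKPC-1, iKPC-3 and iKPC-5, and Crlf1 at 48.9, 0.64 and 0.05 CPM. Their mean of at least 2 CPM thus rests on iKPC-1. Pigr, the receptor that carries antibodies across epithelia, went from 251 ± 219 to 54.5 ± 48.4 CPM (block log2 fold change -1.92 ± 0.25, adjusted p = 0.0108, edgeR). Clec2h, Casp1, Ildr1, Naip1, Fmo5, Ceacam18, Entpd8, Fer1l6 and Myo1a, a motor of the intestinal brush border, were the others named for a fall, from -2.03 to -1.39. Clec2h and Naip1 have near-identical copies and are uncertain.

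Of the 22 Wnt and TCF targets tested, 7 rose and 1 fell with the block (8 and 1 adjusted over the list alone), led by Lgr5, Axin2, Tnfrsf19 and Lef1, against 0 and 0 without the block by either adjustment. The list had a median of 0.54 and a mean of 1.25, with camera adjusted p = 0.00034 and adjusted p = 0.251 with an estimated correlation. Mitosis genes had 28 of 30 higher with the block and 0 lower, and adjusted over the list alone 26 were higher without the block and 30 with it. Top2a, which untangles DNA before division, went from 85.7 ± 46.8 to 220 ± 57.9 CPM, and the list had a median of 1.21, camera adjusted p = 2.36e-34 and adjusted p = 0.176 with an estimated correlation. For S phase and DNA replication 5 of 30 were higher with the block (22 adjusted over the list alone) and 0 lower, including Cdc45, a part of the replicative helicase, at 1.12, with a list median of 0.65, camera adjusted p = 3.5e-16 and adjusted p = 0.251 with an estimated correlation. Mesenchymal markers had 7 of 24 higher with the block and 0 lower (14 and 1 adjusted over the list alone). Sparc, a matrix protein, went from 14.9 ± 6.41 to 67.9 ± 18.9 CPM, and the list had a median of 1.05, camera adjusted p = 4.41e-07 and adjusted p = 0.109 with an estimated correlation. Markers of fibroblasts moved with it: 1 of 5 tested was higher with the block, Islr, which went from 0.183 ± 0.242 to 3.82 ± 1.86 CPM (4 adjusted over the list alone; median 2.33, camera adjusted p = 0.00124, adjusted p = 0.109 with an estimated correlation). Of 31 epithelial markers 7 fell with the block and 0 rose (17 and 0 adjusted over the list alone), with Spint2, a protease inhibitor, going from 712 ± 130 to 443 ± 44.6 CPM. That list had a median of -0.69, camera adjusted p = 4.97e-06 and adjusted p = 0.176 with an estimated correlation. ERK and RAS output missed the camera threshold (adjusted p = 0.0536) and passed it with the block (adjusted p = 0.0281, but adjusted p = 0.665 with an estimated correlation), with Etv4 and Spred1 the 2 members that rose with the block.

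**Figure D2:**
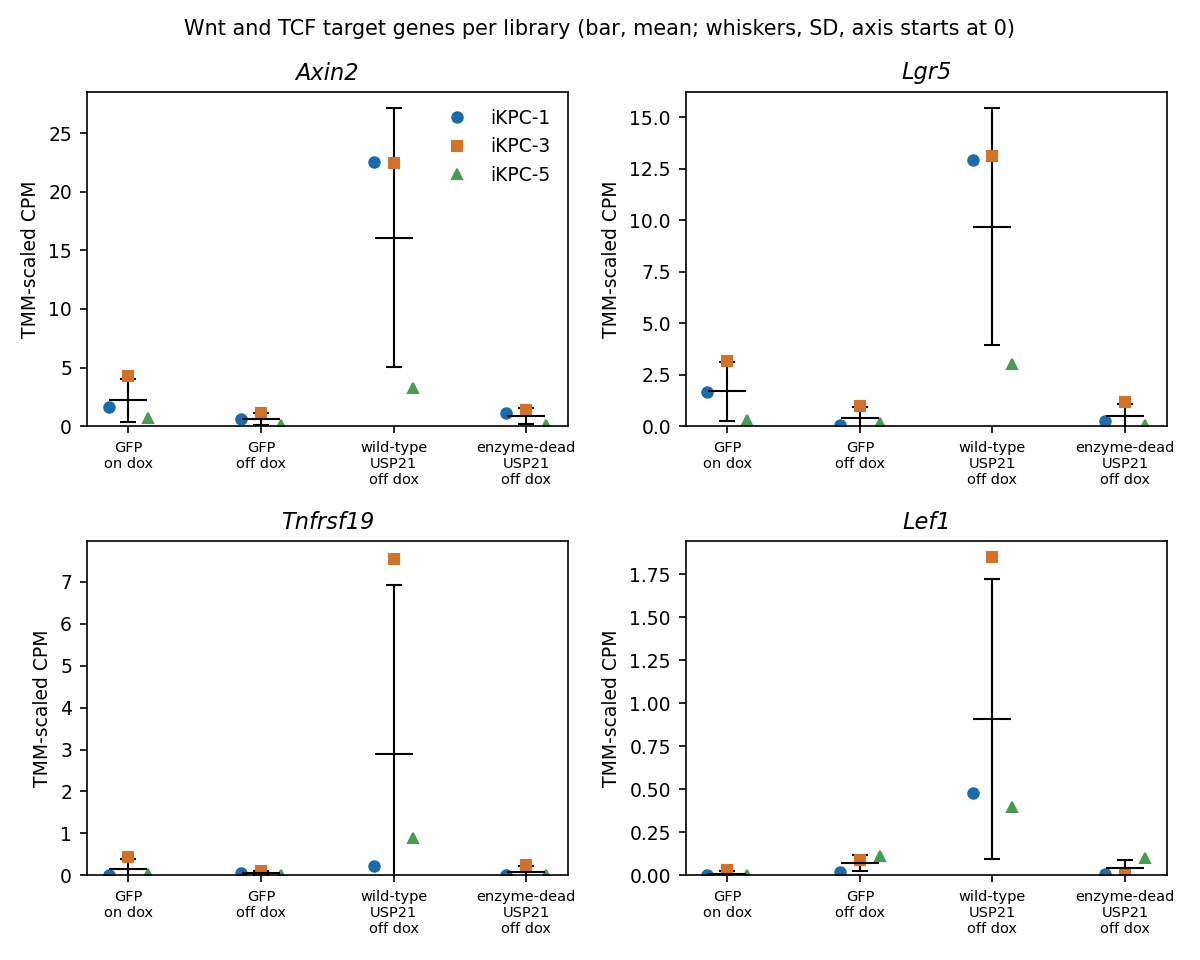
Axin2, Lgr5, Tnfrsf19 and Lef1 in TMM-scaled CPM, per library (coloured points, 1 per cell line) with the group mean (bar) and SD (whiskers, n = 3), in the 4 groups; whiskers are drawn down to 0 only. Axin2 averaged 16.1 CPM with wild-type USP21, 0.855 CPM with enzyme-dead USP21 and 0.601 CPM with GFP off dox.

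With edgeR and no block, 1 gene was higher and 0 were lower with wild-type USP21. An unadjusted p under 0.05 was found for 1027 genes without the block and 3903 with it, against 853 if no gene changed and p were uniform. Without the block, differences between lines count as spread, so that count cannot show how near to chance the effect lies. DESeq2 called 98 higher and 23 lower, and limma-voom called 2 higher and 0 lower. With the cell line as a block edgeR called 666 higher and 503 lower, and without iKPC-1, iKPC-3 and iKPC-5 in turn this became 121 and 139, 226 and 41, and 0 and 0. Of the 67 named genes that passed with the block, 18, 20 and 0 still passed there without iKPC-1, iKPC-3 and iKPC-5. Usp21 did not pass without any 1 of the 6 libraries compared, without all libraries of iKPC-3 or of iKPC-5, or with RLE scaling (0 genes higher in each case).

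The third comparison, enzyme-dead USP21 against GFP, both off dox, asks what the protein changed without its activity. Usp21 was the 1 gene that passed edgeR's test, with or without the block, and 0 genes were lower. Axin2 averaged 0.855 ± 0.691 CPM with enzyme-dead USP21 and 0.601 ± 0.531 CPM with GFP. Wnt and TCF targets missed the camera threshold (adjusted p = 0.375), with 0 of 22 past either test, a median of 0.016 and a mean of -0.12. Mitosis genes stood higher as a list (median 0.57, camera adjusted p = 1.11e-34, adjusted p = 0.541 with an estimated correlation), though 0 of 30 members passed in either test or adjusted over the list alone. Tpx2, a spindle assembly factor, had 33.9 ± 11.9 CPM against 21.7 ± 10.0 CPM with GFP. The list for S phase and DNA replication was also higher (median 0.28, camera adjusted p = 1.83e-12, adjusted p = 0.562 with an estimated correlation). Glycolysis genes were lower as a list (median -0.32, camera adjusted p = 7.3e-08, adjusted p = 0.541 with an estimated correlation), with Gapdh at 1542 ± 138 CPM against 2410 ± 710 CPM. Hypoxia genes and epithelial markers were lower too (medians -0.48 and -0.23, camera adjusted p = 2.1e-07 and 0.00195, and adjusted p = 0.562 for both with an estimated correlation). In each of these lists 0 members passed edgeR's test, with or without the block, or adjusted over the list alone. An unadjusted p under 0.05 was found for 54 genes without the block and 330 with it, against 853 if no gene changed and p were uniform. Counts under 853 mean that p were not uniform, so they do not show the absence of an effect. DESeq2 and limma-voom each called 1 gene higher and 0 lower without the block, and DESeq2 with the block called 26 higher and 24 lower. In edgeR without the block, Usp21 did not pass without any 1 of the 3 GFP libraries off dox, nor without iKPC-3 or iKPC-5.

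The last comparison sets wild-type against enzyme-dead USP21 and asks what differed with the activity of the enzyme. Protein was not measured, so unequal protein levels of both forms cannot be told apart from an effect of the activity. Without the block 0 genes passed edgeR's test, so the named genes come from the test with the cell line as a block, which called 18 higher and 13 lower with wild-type USP21. Axin2 led them, at 16.1 ± 11.1 CPM with the wild-type form and 0.855 ± 0.691 CPM with the enzyme-dead form (block log2 fold change 4.44 ± 0.42, adjusted p = 0.0188, edgeR). Adamts7, a metalloprotease, stood at 9.51 ± 2.05 against 2.18 ± 0.599 CPM (2.15 ± 0.21, adjusted p = 0.0188, edgeR), and Tgfb3, a TGF-beta ligand, at 24.9 ± 11.2 against 7.01 ± 5.01 CPM (2.08 ± 0.28, adjusted p = 0.0361, edgeR). Cd274, which encodes the immune checkpoint ligand PD-L1, was higher by 1.38 ± 0.19 (adjusted p = 0.0361, edgeR). Ptprb, Tuba1a, Cyp1b1, Nebl, Mex3a and Sema4c were the others named as higher, from 0.85 to 1.81. The counting could have split reads between Tuba1a and other tubulin genes, so its value is uncertain. The 10 named as lower ran from -0.95 for Sqrdl, which oxidizes sulfide in mitochondria, to -0.55 for Trpm4. They include the hypoxia-inducible factor gene Epas1 (-0.67 ± 0.09, adjusted p = 0.0294, edgeR), Suox, Tspan15, Tnfrsf21, Sgsm2, Aldh3a2, Anxa13 and Rhpn2.

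Wnt and TCF targets were higher as a list with the wild-type form (median 0.59, camera adjusted p = 1.69e-06, adjusted p = 0.215 with an estimated correlation). Of 22 members, Axin2 alone passed with the block, and adjusted over the list alone 8 were higher and 1 lower there. Mesenchymal markers were higher (median 0.78, camera adjusted p = 2.32e-08, adjusted p = 0.0706 with an estimated correlation) and so were markers of fibroblasts (median 0.77 of 5 genes, camera adjusted p = 0.000432, adjusted p = 0.0706 with an estimated correlation). No member of either passed over all genes, and adjusted over the list alone with the block 9 of 24 and 1 of 5 were higher. Epithelial markers were lower as a list (median -0.47, camera adjusted p = 0.000192, adjusted p = 0.245 with an estimated correlation), with Spint2 at 443 ± 44.6 against 612 ± 102 CPM. Mitosis genes were higher (median 0.64, camera adjusted p = 1.14e-20, adjusted p = 0.245 with an estimated correlation), with 0 of 30 past the test over all genes and 29 higher with the block adjusted over the list alone. For S phase and DNA replication the median was 0.39 (camera adjusted p = 2.67e-09, adjusted p = 0.414 with an estimated correlation). ERK and RAS output was higher by a median of 0.24 (camera adjusted p = 0.0204, adjusted p = 0.627 with an estimated correlation), and it missed the camera threshold without iKPC-1 (adjusted p = 0.13) or iKPC-5 (adjusted p = 0.0535).

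**Figure D3:**
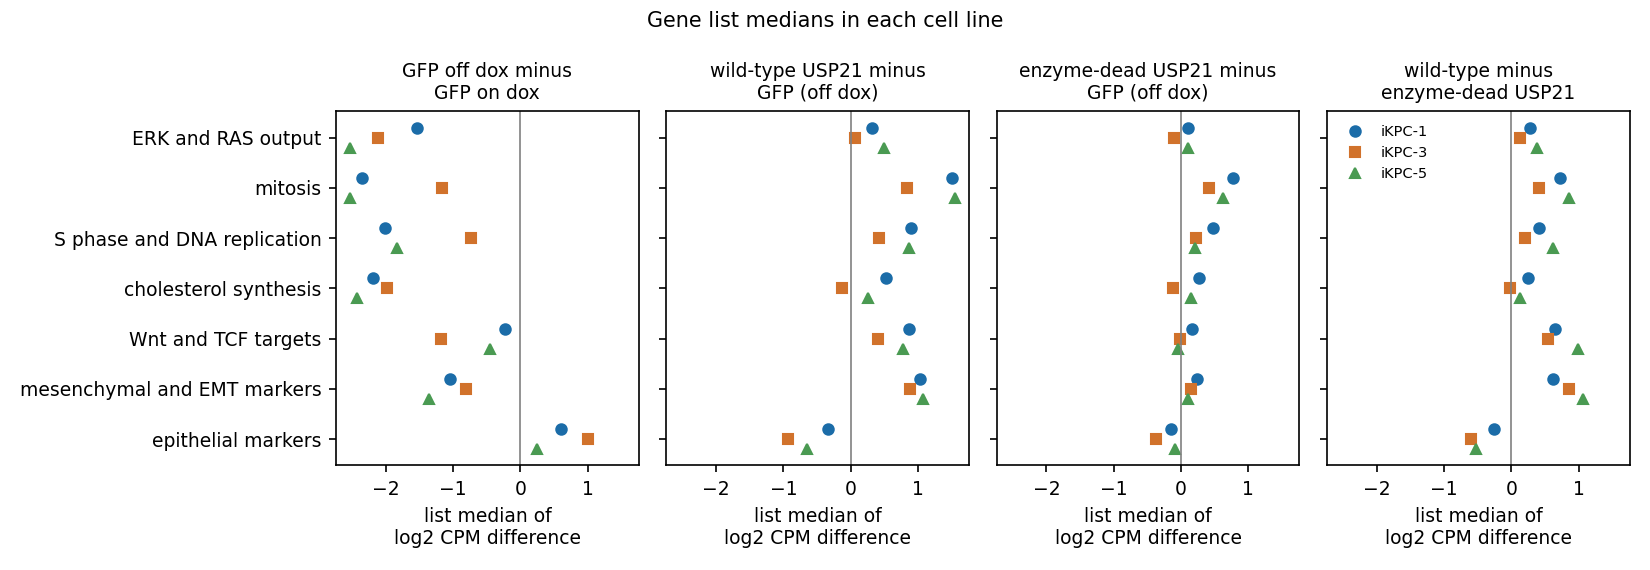
Median log2 CPM difference of the genes of 7 lists (vertical axis), in each cell line (coloured points), for the 4 comparisons (panels). Over the 3 lines the mitosis medians lie below 0 for KRAS* extinction and above 0 in the other 3 panels, and the Wnt and TCF medians lie above 0 for wild-type against enzyme-dead USP21.

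Without the block, edgeR called 0 genes in this last comparison, limma-voom called 0 and DESeq2 called 25 higher and 3 lower. An unadjusted p under 0.05 was found for 414 genes without the block and 2611 with it, against 853 if no gene changed and p were uniform. Without the block, differences between lines count as spread, so a count under 853 does not show the absence of an effect. With the block, leaving out any 1 of the 3 cell lines ended all 31 calls of edgeR. DESeq2 with the block called 591 higher and 474 lower.

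A last question is whether genes that KRAS* raised were those that active USP21 raised without KRAS*. Across 17064 genes, the log2 difference of GFP on dox over GFP off dox was set against that of wild-type over enzyme-dead USP21, which share no library. The difference on dox also holds any effect of the drug itself. Pearson's r across genes was 0.13, 0.108 and 0.272 in iKPC-1, iKPC-3 and iKPC-5, a mean of 0.170 ± 0.089 (SD, n = 3), and no p is given since genes are not independent replicates. Of the 1871 genes that fell on KRAS* extinction, 68.0 ± 2.03% were higher with wild-type than with enzyme-dead USP21. Of the 1671 that rose, 73.0 ± 2.58% were lower with wild-type, while of all genes 47.6 ± 1.37% were higher.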

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

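The tests in this part were chosen only after the data were seen. They cover the level of Usp21, the share of dividing cells, fibroblasts, scaling by total counts, GC content and length, and cell cycle genes. Among the 51 list calls by camera, the median of 1 cell line went against the other two in 4 calls on 3 lists, a difference between lines that was not tested. Lists that missed the camera threshold are not counted here. Cholesterol synthesis genes with wild-type USP21 against GFP had a median log2 difference of -0.125 in iKPC-3, against 0.529 in iKPC-1 and 0.261 in iKPC-5. With enzyme-dead USP21 against GFP the same list stood at -0.112 in iKPC-3, against 0.272 and 0.146. Hypoxia genes with wild-type against enzyme-dead USP21 stood at -0.0921 in iKPC-5, against 1.22 in iKPC-1 and 0.329 in iKPC-3. Endothelium markers in that comparison stood at -0.0106 in iKPC-1, against 0.737 in iKPC-3 and 0.704 in iKPC-5.

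Wnt and TCF targets stood higher with wild-type than with enzyme-dead USP21 in iKPC-1, iKPC-3 and iKPC-5, with list medians of 0.651, 0.544 and 0.988. The tables argue against less Usp21 transcript in the enzyme-dead cells, since the lowest ratio of Usp21 CPM, enzyme-dead to wild-type, was 0.993 over the 3 lines, although protein was not measured. They also argue against a bias by GC content or transcript length, since 97.7% of the list median with the block was left after correction (camera adjusted p = 5.03e-07). A larger share of dividing cells as the whole cause was examined in enzyme-dead USP21 against GFP, both off dox. There mitosis genes were also higher in iKPC-1, iKPC-3 and iKPC-5 (0.770, 0.409 and 0.623), while the 22 Wnt targets stood at 0.159, -0.0202 and -0.0504. The ratio of both lists for wild-type against enzyme-dead USP21 predicts 0.646 ± 0.099 (SD, n = 3) for these Wnt medians. The measured ones fell short of it by 0.616 ± 0.129, more than the SD of 0.419 over the list members in enzyme-dead USP21 against GFP. The spread of members behind that ratio was left out, and the rise of mitosis genes passed neither fry nor, for any member, edgeR's test. Both comparisons share the enzyme-dead libraries, so chance values there add to this shortfall. The Wnt list thus did not rise as the mitosis list did, but the shortfall cannot decide whether cell division was the whole cause. Against GFP cells on dox, whose mitosis genes stood higher in every line (wild-type minus GFP on dox, -0.888, -0.333 and -0.949), the 22 Wnt targets were higher by 0.202 ± 0.213 (SD, n = 3), less than their spread. The 7 targets that rose with the block, Axin2 and Lgr5 among them, were higher there by medians of 2.95, 2.05 and 2.29, though they were chosen for a rise in the same wild-type USP21 libraries. Cell division as a part or the whole of the cause stays open, and that the activity of USP21 raises Wnt targets is a hypothesis, found and tested on the same data.

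Mesenchymal markers stood higher and epithelial markers lower with wild-type USP21 than with GFP in all 3 lines, with medians of 1.03, 0.886 and 1.08 and of -0.344, -0.929 and -0.647. Fibroblasts in these cultures would bring abundant collagen and decorin transcripts, but the summed CPM of Col1a1, Col1a2, Col3a1, Dcn, Lum and Postn was at most 10.4 in the wild-type USP21 libraries, with Col1a1 at 8.54 the most abundant; 4 of the 6 are also in the mesenchymal list. That sum was higher than with GFP off dox in each line, at 7.41 against 0.703 in iKPC-1, 10.4 against 2.13 in iKPC-3 and 4.38 against 1.21 in iKPC-5, and it stood at 10.0 with enzyme-dead USP21 in iKPC-3. These levels argue against fibroblasts as the source of the whole shift, in which Sparc alone went from 14.9 to 67.9 CPM, and leave open a small number of fibroblasts or low expression of these genes by the cells themselves. Scaling was tested with total counts alone, which left epithelial markers at -0.602 and mesenchymal markers at 1.13, and a correction for GC content and length kept 94.6% of the gap between both medians. A shift of the cells themselves towards a mesenchymal state with USP21 is a hypothesis that these tests leave in place, found and tested on the same data.

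The effects of KRAS* and of active USP21 correlated positively across genes in each line. A correction for GC content and length kept 100.6% of the mean correlation, which argues against that bias. Without 963 cell cycle genes, those of the cell cycle lists and those correlated with mitosis genes above 0.8, 76.6% of the mean correlation was left. The share left within iKPC-1, iKPC-3 and iKPC-5 was 63.8%, 78.7% and 81.9% (SD 9.64, n = 3). How much of the remainder comes from cells that divide more cannot be told apart from other shared effects, since any threshold for cell cycle genes leaves some in. Genes outside the lists that correlated negatively with mitosis genes all stayed in.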

How the results depend on the processing

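Chosen only after the results were seen were the tests with total count scaling, with the block without each line, with GC and length correction and without cell cycle genes. With the filter of 1 CPM, without a filter and with limma-voom, the counts of calls stayed within 1.5 times, except that limma-voom called 2 genes higher with wild-type USP21; with RLE scaling the same held except for 0 genes higher there. DESeq2 called 2579 genes higher on KRAS* extinction, 98 higher and 23 lower with wild-type USP21, and 25 higher and 3 lower for wild-type against enzyme-dead USP21. The replicate block gave 4606 higher and 4199 lower on KRAS* extinction, 666 and 503 with wild-type USP21, and 18 and 13 for wild-type against enzyme-dead USP21. The replicate block in DESeq2 gave 4864 and 4506, 1305 and 1184, 26 and 24 (enzyme-dead USP21), and 591 and 474. The replicate block with GC and length correction gave 4544 and 4139, 641 and 544, and 17 and 14 in the first, second and last comparison. Without iKPC-1 the replicate block gave 4242 and 3957 on extinction and 121 and 139 with wild-type USP21. Without iKPC-3 it gave 3059 and 3050, then 226 and 41, and 0 higher with enzyme-dead USP21. Without iKPC-5 it gave 2552 higher on extinction, 0 higher with wild-type USP21 and 0 with enzyme-dead USP21. A fit of only the 2 groups compared gave 639 and 913 on extinction and 0 higher for each form of USP21; it has fewer samples from which to take the spread. Total count scaling gave 2896 and 1137 on extinction. Leaving out libraries or lines without the block, calls on extinction ran from 125 to 1630 higher and from 140 to 1982 lower, and from 0 to 1 higher for each form of USP21 against GFP, with fewer samples in each. Apart from fewer samples, the cause of these shifts was not tested. The relation across genes kept its sign and stayed within 1 SD in all 9 alternatives, from 0.119 without iKPC-5 to 0.246 with a filter of 1 CPM. The named genes called without the block kept their sign in each alternative, which adds little since they were chosen for passing in the same libraries. Of those called with the block, from 64 to 67 of 67 with wild-type USP21 and from 19 to 20 of 20 for wild-type against enzyme-dead USP21 kept theirs. Without iKPC-1 the cholesterol synthesis median with enzyme-dead USP21 was -0.027, against 0.056. Of the 51 list calls, 51 were lost with an estimated correlation, 42 with fry, 26 with fry and the block, 8, 6 and 7 without iKPC-1, iKPC-3 and iKPC-5, 3 with total counts and 0 with RLE scaling. Fry, which does not compare a list with other genes, called 10, 1, 0 and 0 lists in the 4 comparisons and 21, 7, 0 and 6 with the block. Of the lists that camera called, 8, 1, 0 and 0 passed fry as well, and 13, 6, 0 and 6 passed it with the block. The upper limit that a count of 0 allows lay at or under 0.0378 CPM in each library, so depth limits genes near that level.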

Other observations

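On KRAS* extinction, further lists went both ways or moved little. TGF-beta and SMAD targets had 4 of 24 lower, with Tgfb1 at -3.09, and 3 higher, with Id3 at 1.95 (5 and 3 adjusted over the list alone, 13 and 3 with the block); camera gave adjusted p = 0.0377, adjusted p = 0.558 with an estimated correlation and adjusted p = 0.149 without iKPC-5. Ribosomal proteins had 0 of 32 past edgeR's test and 21 lower with the block, with a median of -0.31 (camera adjusted p = 0.00045, adjusted p = 0.558 with an estimated correlation), and scaling by total counts gave a median of -0.053 and ended that call (adjusted p = 0.0735). Macropinocytosis genes had 6 of 34 lower, with Elmo2 at -1.26, and 3 higher, with Elmo1 at 2.55, and both encode partners of DOCK proteins (14 and 6 with the block, camera adjusted p = 0.0851). Lysosome and autophagy genes had 4 of 36 lower, with the cholesterol transporter gene Npc1 at -1.76, and 3 higher, with Ctsa at 0.95 (7 and 17 with the block, adjusted p = 0.187). Oxidative phosphorylation had 4 of 34 higher and 2 lower (14 and 5 with the block, 0.127), YAP and TAZ targets 5 of 29 each way (8 higher and 9 lower with the block, 0.829) and p53 targets 4 of 26 higher, with Fas at 3.84, and 6 lower, with Cdkn1a at -2.46 (5 and 11 with the block, 0.0979). Histone genes (14 tested, 0.203) and markers of fibroblasts (5 tested, 0.829), leukocytes (8 tested, 0.829), endothelium (9 tested, 0.865) and pancreatic acini and islets (2 tested, 0.506) had 0 members past edgeR's test, and 1, 1, 2, 0 and 0 higher and 3, 1, 1, 2 and 1 lower with the block, in that order. The p in parentheses without other words are camera adjusted p. Median and mean differed in sign for the YAP and TAZ list (-0.13 and 0.0022), for markers of fibroblasts (1.05 and -0.024) and for markers of leukocytes (-0.089 and 0.52).

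With wild-type USP21 against GFP, camera also set higher the lists for NF-kappaB (median 0.35, adjusted p = 0.00034, adjusted p = 0.51 with an estimated correlation), YAP and TAZ (0.23, 0.00034, 0.251) and MYC targets (0.26, 4.97e-06, 0.51), and lower those for lysosome (-0.17, 0.00124, 0.251) and oxidative phosphorylation (-0.097, 0.0264, 0.51), each with its values in that order. With the block 3 of 31 NF-kappaB genes rose, Cxcl15, Nfkbie and Nfkb2, and 7 of 29 YAP and TAZ targets rose, among them Thbs1 at 2.06 and Tgfb2 at 1.48, and 1 fell. The block also called Cdk4 of the MYC targets and Idi1 of cholesterol synthesis higher, and lower Sdhd of oxidative phosphorylation and 5 of 36 lysosome genes, among them Hexa and Glb1. Without the block 0 members of these lists passed over all genes. Cholesterol synthesis was higher by a median of 0.20 (camera adjusted p = 0.0304, 0.826 with an estimated correlation), which did not pass without iKPC-1 (0.815) or iKPC-5 (0.0981), and oxidative phosphorylation did not pass without iKPC-3 (0.238), with total counts (0.292) or with GC and length correction (0.388).

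With enzyme-dead USP21 against GFP, camera set ribosomal proteins (median 0.083, adjusted p = 0.000677), MYC targets (0.085, 0.0117) and cholesterol synthesis (0.056, 0.0117) higher and interferon response (-0.11, 0.00992) and histone genes (-0.21, 0.0117) lower, and with an estimated correlation the adjusted p ran from 0.619 to 0.677. Each of these calls ended without at least 1 cell line: ribosomal proteins without iKPC-3 (0.0795), MYC targets without iKPC-1 or iKPC-3 (0.145 and 0.14), cholesterol synthesis without iKPC-1 or iKPC-5 (0.781 and 0.103), interferon response without iKPC-1 (0.145) and histone genes without any 1 line (0.0935, 0.0832 and 0.127). With the block, lists for oxidative phosphorylation (0.0142), lysosome (0.0463) and YAP and TAZ (0.0463) passed camera as well, but with an estimated correlation their adjusted p was 0.737, 0.804 and 0.56.

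Between wild-type and enzyme-dead USP21, camera set higher the lists for NF-kappaB (median 0.29, adjusted p = 0.000192, 0.503 with an estimated correlation), MYC targets (0.16, 8.99e-05, 0.547), YAP and TAZ (0.13, 0.000569, 0.245), hypoxia (0.56, 0.00195, 0.573), endothelium markers (0.65, 0.00654, 0.136) and histone genes (0.43, 0.0277, 0.503), and lower oxidative phosphorylation (-0.12, 7.79e-05, 0.245) and lysosome (-0.16, 0.00276, 0.249). Hypoxia did not pass without iKPC-1 (0.774), MYC targets without iKPC-5 (0.182), endothelium markers without iKPC-3 (0.092) and histone genes without iKPC-1 or iKPC-3 (0.154 and 0.4), with the block (0.081) or with total counts (0.0731). TGF-beta and SMAD targets passed with the block only (0.0351, but 0.652 with an estimated correlation).

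The tests of both hypotheses that follow were chosen only after the result was seen. Several genes that rose on KRAS* extinction or fell with wild-type USP21 act in the intestinal brush border, so a shared intestinal differentiation program was tested as a hypothesis on 19 tested genes of such a list that had not been seen in the results, of which 1 is also in another list. Their median rose on extinction in each line (0.712, 1.71 and 1.31), with 3 genes higher and 0 lower by edgeR's test (11 and 1 with the block), and was lower with wild-type than with enzyme-dead USP21 in each line, the highest being -0.258, with 0 genes past edgeR's test with or without the block. This is what the hypothesis predicts, but it is not specific to these genes, since 73.0% of all genes that rose on extinction were lower with wild-type USP21.

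Cdkn2a and Cdkn2b, neighbouring genes that encode inhibitors of the cell cycle, were named after their values were seen. Over the 4 libraries of each line Cdkn2a averaged 72.8 CPM in iKPC-1, 0.0907 in iKPC-3 (35 reads) and 0 in iKPC-5, at least 2201-fold lower than in iKPC-1 with a floor of 3 reads per library. Cdkn2b averaged 91.5, 0.127 and 0 CPM, at least 2765-fold lower in iKPC-5. The hypothesis that both copies of a stretch of chromosome that reaches the nearest expressed neighbours were lost was tested on Mtap and Tusc1. In gene order counted from the pair they lie at places -4 and 28, so the side of Tusc1 was not tested close by. The highest fold of iKPC-1 over another line was 1.98, for Mtap, which argues against loss of both copies of either gene. Loss of 1 copy of Mtap, a smaller loss between these neighbours, or silencing of Cdkn2a and Cdkn2b stays open and was not tested.

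For each comparison of 3 against 3 libraries there are only 10 splits of the 6 libraries, and 4 that keep each line paired, too few for a share under 0.05. As many genes as the real split were called by 1, 1, 2 and 10 of the 10 splits in the 4 comparisons, with 3542, 1, 1 and 0 genes for the real split and at most 0, 0, 1 and 1 for any other. With the block the real splits gave 8805, 1169, 1 and 31 genes and the others at most 0, so that 1 of the 4 splits, the real one, reached each count.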
